A study of Mus musculus with 2 samples.

How the data were processed

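In situ Hi-C with DpnII digestion, 1% formaldehyde crosslinking and biotin labelling was performed on fluorescence-sorted, Olfr17-positive neurons from the olfactory epithelium of adult 129P2/OlaHsd mice of both sexes, per the labels. The 2 biological replicates (23000 and 20000 cells) form 1 group. Hi-C ligates DNA ends that lie close together in the nucleus, and a domain boundary is a position across which contacts are depleted.

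The authors combined the contact lists of both replicates into 1 contact matrix on GRCm38 and called boundaries on it, per the labels' design text and the submitters' processing notes. The deposited list gives each boundary a bin of 5 kb, a class and a boundary score. The score has no unit stated by the authors and is compared only within this list. In the values, all Weak scores were at most 0.4996 and all Strong scores at least 0.5002, so the class is a threshold on the score, and the lowest score was 0.2. The boundary caller, its window and its version, the aligner, its filters and the number of contacts are not given in the sources used here. The contact matrix, the insulation track and the compartment track were not used here. Since the list was made from both replicates, the spread between animals could not be measured, and the p-values below concern positions in 1 map.

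Genes came from the GENCODE M21 annotation and sequence from the GRCm38 reference, the same build as the list. The 21728 protein-coding genes with their annotated 5' ends as TSSs, and 53843 genes of any type as an alternative, were used on the autosomes and X. Coordinates are 1-based. A boundary's position was the midpoint of its bin. Density was counted per Mb of sequenced bases (2559 Mb without N). The reference is of the C57BL/6J strain and the mice were 129P2/OlaHsd, so structural differences between the strains, in OR clusters among other places, are not seen in these coordinates.

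Enrichment was tested against 10000 circular shifts of the boundaries along the sequenced bases of each chromosome, with two-sided permutation p-values and 95% ranges of the shifts. Comparisons matched on distance to TSSs used 10000 binomial draws instead. Their rates came from random positions in the same distance classes, and they treat positions as independent. Errors of densities are jackknife standard errors over chromosomes, and spacing has a bootstrap interval over chromosomes. CTCF matches were found by exact search of both strands for the consensus (88670 core matches and 6562 strict ones). These are sequence matches and not measured binding. Correlations across chromosomes used 100000 permutations. A gene cluster was a run of at least 5 genes of a family, by symbol, with neighbouring TSSs under 500 kb apart, and an edge counted as having a boundary within 50 kb. P-values for 10 families, the OR family included, and for 12 gene lists were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Each gene list was compared with 10000 random lists of equal size, matched on the decile of the number of protein-coding TSSs within 500 kb. Of the listed symbols, Znf143 matched no gene, and Zfp143 was used.

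Read uniqueness was estimated from reads of 100 bases taken every 500 bases of the reference and aligned back to it with minimap2 2.31. A read with a mapping quality of at least 30 counted as unique. Well-mapped boundaries were those with at least 80% unique reads within 50 kb. The authors' read length and mapping filter were not known, so this measures the reference and not their reads.

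The gene lists, the cluster rules, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the nearest genes of the 10 boundaries with the highest scores; members of the mature OSN and regulator lists with a boundary within 10 kb and the 3 farthest of each; at most 3 nearest members of other lists; Olfr17 and Olfr16; the 5 largest OR clusters and those of at least 10 genes without a boundary; and Omp, Lhx2, Ldb1, Ebf1, Adcy3, Ctcf and the Hoxa, Hoxd and protocadherin clusters. Of other genes and clusters named, C1qb, C1qc, Hbb-bt, Dlg2, Taf7, the Hoxb and Hoxc clusters and those in the widest intervals were chosen after their values were seen. The alternatives were Strong boundaries alone, the boundaries with the highest scores, autosomes alone, no boundaries near assembly gaps, other distances, other cluster rules, other random backgrounds, a stricter motif and each chromosome left out in turn.

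The tests were run on simulated data, with 100 simulated maps of 7576 boundaries and 200 shifts each. Before any effect was planted, boundaries were placed independently and at random on each chromosome, unlike the spacing of the real list. The rates for the TSS and OR cluster tests hold for such maps only. With no effect planted, the TSS test made a call in 3% of maps, the test of density inside OR clusters in 3% and the test of OR cluster edges in 6%. With boundaries planted at TSSs, moved out of OR clusters and planted at edges, these tests made a call in 100%, 54% and 99% of maps. The planted density ratio in OR clusters averaged 0.791, so the density test misses many effects of that size. Random lists of 20 and 80 genes were called in 1% and 8% of 100 simulations, by unadjusted permutation p. Lists of these sizes with exactly 50% of genes within 25 kb of a boundary were called in 100%. This share was the same in every planted list. The result therefore gives no power for smaller shares, for lists under 20 genes or after adjustment. The analysis used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.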

Results

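Chromosome folding was measured by in situ Hi-C in olfactory sensory neurons (OSNs) of adult mice that had been sorted for expression of 1 olfactory receptor (OR) gene, Olfr17, also called P2. Each mature OSN expresses 1 OR gene out of a family that lies mostly in tandem clusters, so the sorted cells share the OR gene they use. The 2 biological replicates held 23000 and 20000 cells and form 1 group. The values analysed here are the domain boundaries that were called on the contact matrix of both replicates combined, so there is 1 list of boundaries and no comparison between replicates or with another cell type. The number of contacts behind the list is not given in the sources used here and the depth is therefore unknown. Chromosomes and genomic positions are the repeated units below, and every p-value describes positions within this 1 map, not variation between animals.

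The map held 7576 boundaries, each a bin of 5 kb on the autosomes or the X chromosome. The authors' class was Strong for 4045 of them (53.4%) and Weak for 3531 (46.6%). The authors' boundary score, which has no stated unit, had a median of 0.545 over all boundaries, 0.936 for Strong and 0.301 for Weak ones, and reached 4.38. Boundaries lay at 2.96 ± 0.0555 per sequenced Mb (jackknife standard error over 20 chromosomes). The median distance between neighbouring boundaries was 260 kb (95% bootstrap interval 255 to 270), with quartiles of 180 and 395 kb. The same numbers of boundaries placed at random on each chromosome gave a median of 234 kb (95% range 228 to 239, two-sided permutation p = 0.0001, the smallest value that 10000 draws can give). For Strong boundaries alone the order was the opposite, with a median of 385 kb against 428 kb at random (permutation p = 0.0001). The 3788 boundaries with the highest scores also lay closer together than at random, at 410 against 457 kb (permutation p = 0.0001). Random placement allows any distance, while the shortest distance between neighbours among all boundaries was 35 kb. Any minimum distance set by the caller is unknown here and could raise the median of the list.

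Gene-rich chromosomes tended to hold more boundaries per Mb. Chromosome 11 had the highest density, 3.59 per Mb, beside 13.8 protein-coding genes per Mb, and among the autosomes chromosome 14 had the lowest, 2.52 per Mb beside 7.43 genes per Mb. Single chromosomes departed from this order: chromosome 7, with the most genes per Mb (14.3), had 2.96 boundaries per Mb, and chromosome 18, with 5.87 genes per Mb, had 3.11. Across the 20 chromosomes the boundary density correlated with gene density (Pearson r = 0.656, permutation p = 0.00129; Spearman rho = 0.698, permutation p = 0.00086). Without chromosomes 7 and 11, which lie farthest from the median gene density, r was 0.650 (permutation p = 0.00411).

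The X chromosome had the lowest share of Strong boundaries of all chromosomes. Of its 407 boundaries, 128 were Strong (31.4%), against a mean of 54.5% ± 4.13 (SD over 19 autosomes, range 47.5 to 62.2%). The median score was 0.366 on X and 0.558 ± 0.0462 on the autosomes (SD). Boundary density was 2.49 per Mb on X and 3.0 ± 0.222 per Mb on the autosomes. Each of the 20 chromosomes was ranked by how far it lay from the mean of the others. By this rank of X, the exact two-sided p was 0.05 for the Strong share and for the median score, the smallest this comparison allows. The exact p was 0.1 for density, where X was the lowest (lowest autosome 2.52 per Mb) but another chromosome lay farther from the others. For median spacing, 290 kb on X and 263 ± 17.6 kb on the autosomes (SD), the exact p was 0.15. Read uniqueness was also lower on X, at 74.3% of simulated reads against 81.9 to 91.5% on the autosomes.

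Transcription start sites (TSSs) of protein-coding genes were concentrated at boundaries. A TSS lay within 10 kb of 1962 boundaries (25.9%), against 14.3% of boundaries shifted along their chromosomes (95% range 13.5 to 15.1), a ratio of 1.82 (two-sided permutation p = 0.0001). The share was 14.8% in the lowest quintile of boundary score, 22.2% and 27.0% in the next ones, and 33.4% and 32.1% in the fourth and the highest. The median score was 0.697 with a TSS within 10 kb and 0.490 without one (permutation p = 0.0001).

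Matches to the core consensus of CTCF, the zinc finger protein that marks domain borders together with cohesin, were also concentrated at boundaries. A match to CCANNAGRKGGC lay within 10 kb of 4396 boundaries (58.0%), against 41.5% after shifting (95% range 40.3 to 42.6), a ratio of 1.40 (two-sided permutation p = 0.0001). Against random positions at the same distances from TSSs, where 46.7% had a match, the ratio was 1.24 (p = 0.0001 from binomial draws). The draws treat boundaries as independent. The stricter consensus CCASYAGRKGGCRS lay near 13.8% of boundaries and 4.84% of shifted ones, a ratio of 2.86 (permutation p = 0.0001). Matches within 10 kb pointed away from the boundary, into the domains on both sides, more often than towards it: 45.3% of those to the left of the midpoint and 55.7% of those to the right were on the plus strand (odds ratio 1.52, Fisher's exact p = 1.09e-22). For the stricter consensus the shares were 35.6% and 65.1% (odds ratio 3.37, Fisher's exact p = 3.37e-24). Neighbouring matches are not independent of each other, so these Fisher's p-values are too small. The share of boundaries with a core match was 40.5% in the lowest score quintile, 48.6% and 61.5% in the next ones, 70.3% in the fourth and 69.2% in the highest. Both features lay within 10 kb of 1414 boundaries (18.7%, median score 0.721), and neither of 2632 (34.7%, median score 0.384).

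**Figure D1:**
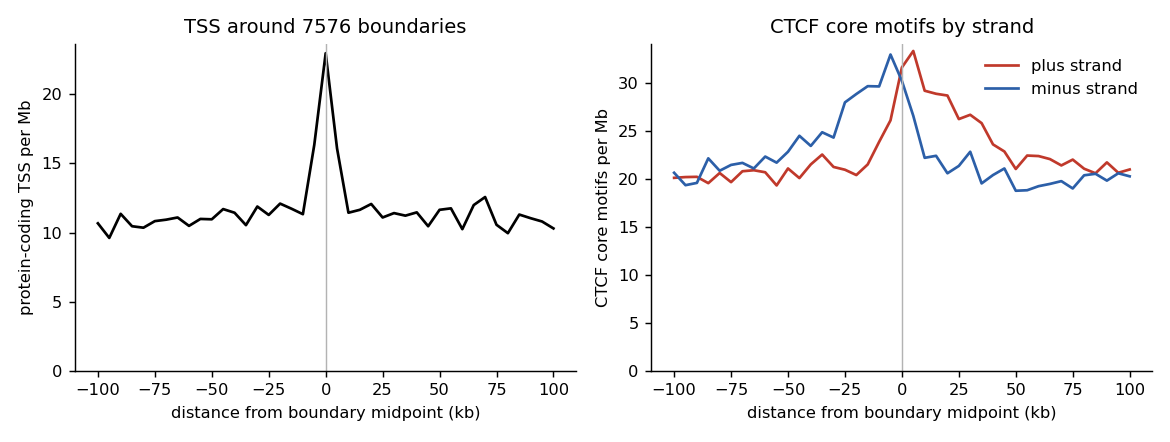
Left, protein-coding TSSs per Mb against distance from the midpoints of the 7576 boundaries in kb; right, CTCF core matches per Mb on the plus and the minus strand. TSSs peak at the midpoint, and minus-strand matches are more frequent to its left and plus-strand matches to its right.

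The 10 boundaries with the highest scores were all Strong and all had a CTCF core match within 10 kb. The highest, with a score of 4.38, lay on chromosome 1 at 88305001 to 88310000 (GRCm38) within Trpm8, the gene of the cold-sensing ion channel, 29.8 kb from its TSS. The next nearest genes were Sfi1 on chromosome 11 (score 4.03, 4.04 kb), Pop4 on chromosome 7 (3.87, 41.1 kb) and Pdcl on chromosome 2 (3.42, 6.83 kb). Simulated reads around the Sfi1 and Pop4 boundaries were unique for 71.9% and 62.9% of positions, below the limit of 80% for well-mapped sequence that the other 8 met. The Pdcl boundary, at 37350001 to 37355000, lay 19.7 kb outside the end of the OR cluster from Olfr334-ps1 to Olfr368. The others, by nearest protein-coding TSS, were Ccdc90b at 464 kb, Gm527 at 15.4 kb, Ppp2r5c at 39.6 kb, Eif1 at 2.38 kb, Jrkl at 23.3 kb and Trrap at 0.231 kb. The Ccdc90b boundary lay within Dlg2.

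The edges of OR gene clusters coincided with boundaries. The annotation gave 34 clusters with 1350 of 1407 OR genes on 15 chromosomes. Of their 68 edges, 44 (64.7%) had a boundary within 50 kb, against 20.4 edges (30.1%, 95% range 13 to 28 edges) after shifting, a ratio of 2.15 (two-sided permutation p = 0.0001, 0.0005 after Benjamini-Hochberg adjustment over 10 gene families). Boundary density was 8.82 per Mb in the 50 kb outside the edges (95% Poisson interval 5.95 to 12.6), 4.24 per Mb (2.32 to 7.12) in the 50 kb inside them and 0.714 per Mb (0.0865 to 2.58) from 50 to 100 kb inside. A boundary lay within 50 kb of both edges at 11 clusters and of neither edge at 1. The ratio at the edges was 3.32 with Strong boundaries alone (permutation p = 0.0001).

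**Figure D2:**
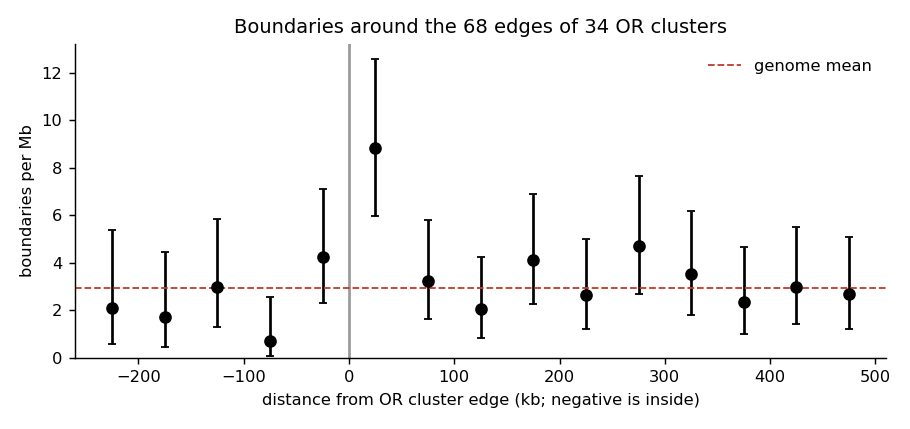
Boundaries per Mb (vertical axis) against distance in kb from the 68 edges of OR gene clusters, with negative distances inside the cluster; bars are 95% Poisson intervals and the dashed line is the genome mean of 2.96 per Mb. The highest density, 8.82 per Mb, is in the 50 kb outside the edge.

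Inside the OR clusters, which span 30.6 sequenced Mb, there were 74 boundaries, or 2.42 ± 0.217 per Mb (jackknife standard error over chromosomes). Shifted boundaries gave 93.5 (95% range 78 to 110), a ratio of 0.791 (two-sided permutation p = 0.0224), and this did not pass after adjustment over the 10 families (permutation p = 0.112). The ratio was 1.01 against windows of equal length and GC content (73.5 boundaries, 95% range 61 to 86, permutation p = 1). With Strong boundaries alone the ratio to shifted boundaries was 0.511 (permutation p = 0.0015), while with all boundaries but without chromosome 2, 9 or 11 the unadjusted permutation p was 0.112, 0.0665 or 0.0716. Boundaries inside OR clusters had lower scores than those elsewhere, with a median of 0.385 against 0.547 (two-sided permutation p = 0.0081), and 36.5% of them were Strong against 53.6%. Among Strong boundaries alone, the median was 1.07 inside and 0.936 outside (permutation p = 0.274). Of the 74 boundaries inside, 14 lay within 50 kb of an edge and count as edge boundaries too. The density ratios, scores and Strong shares inside are therefore not those of the interior alone, which was not tested apart. Simulated reads were unique for 80.1% of the positions inside OR clusters and for 86.9% genome-wide.

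The OR cluster with most genes, from Olfr987 to Olfr1274-ps on chromosome 2 (85330779 to 90403897), held 287 OR genes and 11 boundaries in 5.07 Mb. The cluster from Olfr543 to Olfr692 on chromosome 7 held 156 OR genes and 9 boundaries, with a Strong boundary of score 2.54 at 5.92 kb from its start. The cluster from Olfr160 to Olfr986 on chromosome 9 held 123 OR genes and 4 boundaries, and its longest stretch without one was 1119 kb. Its edges had Strong boundaries at 36.5 kb (score 1.32) and 7.37 kb (score 2.89). On chromosome 19 the cluster from Olfr1417 to Olfr1505 held 91 OR genes and 6 boundaries, and on chromosome 10 the one from Olfr9 to Olfr827 held 67 OR genes and 3 boundaries. Of the 24 clusters with at least 10 genes, 3 had no boundary inside. These ran from Olfr522 to Olfr542-ps1 on chromosome 7 (25 genes, 562 kb), from Olfr30 to Olfr311 on chromosome 11 (23 genes, 390 kb) and from Olfr62 to Olfr1328 on chromosome 4 (15 genes, 280 kb).

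Olfr17, the receptor the cells were sorted for, lies on chromosome 7 at 107093220 to 107099808, in the cluster of 28 OR genes from Olfr693 to Olfr716 (106675005 to 107150581). The 1 boundary inside this cluster was Strong (107005001 to 107010000, score 1.36) and lay 85.7 kb to the left of the Olfr17 TSS. The next boundary on the other side, a Weak one with a score of 0.367, lay 519 kb to the right, beyond the end of the cluster. The interval between them was 605 kb long and held the TSSs of 6 OR genes. Olfr16, an OR gene on chromosome 1 (172950409 to 172958357), had a Strong boundary 243 kb to its left (score 0.755) and a Weak boundary 147 kb to its right (score 0.224).

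**Figure D3:**
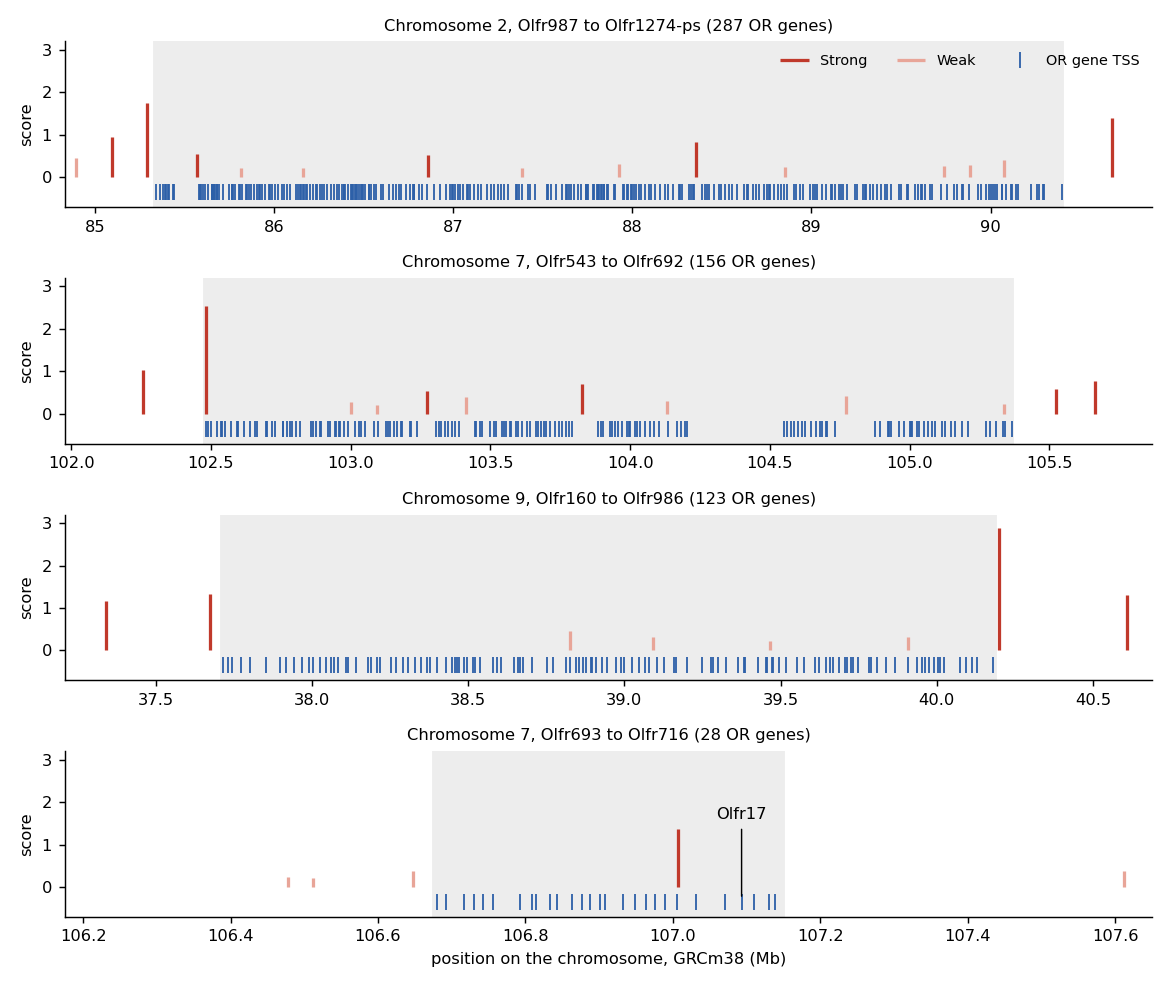
Boundaries (vertical lines, height is the authors' score; dark for Strong, light for Weak) and OR gene TSSs (ticks) along 4 OR clusters (shaded) and 500 kb on each side, with position in Mb on the horizontal axis. The chromosome 9 cluster has Strong boundaries of score 1.32 and 2.89 at its edges and 4 Weak ones inside, and Olfr17 lies 85.7 kb to the right of a Strong boundary of score 1.36.

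Among the other clustered gene families, vomeronasal receptor genes and Cyp2 genes stood apart from shifted boundaries. The 16 vomeronasal receptor clusters, whose 303 genes encode pheromone receptors, held 37 boundaries in 22.0 Mb against 65.7 after shifting (95% range 51 to 80), a ratio of 0.563 (adjusted permutation p = 0.003). With Strong boundaries alone the ratio was 0.330 (adjusted permutation p = 0.007). Against GC-matched windows it was 0.687 (unadjusted permutation p = 0.0018). Simulated reads were unique for 55.9% of positions in these clusters, and among boundaries in well-mapped sequence the ratio was 0.788 (unadjusted permutation p = 0.27). That value, from only 17 boundaries inside, lies within the range of the shifts, so low read uniqueness may account for the lower density. A lack of CTCF core matches may too, since these clusters held fewer than after shifting (ratio 0.402, unadjusted permutation p = 0.004). Boundary number was not compared at equal motif density, and read uniqueness and core matches were not separated from each other. Of the 32 edges of vomeronasal clusters, 17 had a boundary within 50 kb against 9.49 after shifting, a ratio of 1.79 (adjusted permutation p = 0.0193). This call was lost at distances of 25 kb (ratio 1.47, adjusted permutation p = 0.539) and 100 kb (ratio 1.09, adjusted permutation p = 0.951).

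All 8 edges of the 4 clusters of Cyp2 genes, which encode cytochrome P450 enzymes, had a boundary within 50 kb, against 2.41 after shifting (ratio 3.31, adjusted permutation p = 0.0005). At 25 kb the ratio was 3.27 (adjusted permutation p = 0.0818) and at 100 kb 1.8 (adjusted permutation p = 0.0463). The 18 clusters of Zfp zinc finger genes had a boundary at 17 of 36 edges (ratio 1.56, adjusted permutation p = 0.0867), and at 100 kb this passed (ratio 1.40, adjusted permutation p = 0.0463). It also passed with Strong boundaries alone (ratio 1.93, adjusted permutation p = 0.0354), but not with the highest-scoring boundaries (ratio 1.55, adjusted permutation p = 0.26) or at 25 kb (ratio 1.28, adjusted permutation p = 0.683). Defensin clusters had one at 5 of 8 edges (ratio 2.13, adjusted permutation p = 0.114), and with Strong boundaries alone the ratio was 4.09 (adjusted permutation p = 0.015). Keratin, histone, serpin, clustered protocadherin and Hox gene clusters did not differ from shifted boundaries beyond the threshold, with edge ratios of 1.63, 2.37, 1.8, 1.6 and 0.780 (adjusted permutation p from 0.125 to 1). Their density ratios were 1.02, 1.83, 0.793, 0.704 and 1.25, and those of the Zfp, Cyp2 and defensin clusters were 0.958, 1.15 and 0.367, none past the threshold (adjusted permutation p from 0.397 to 1).

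**Figure D4:**
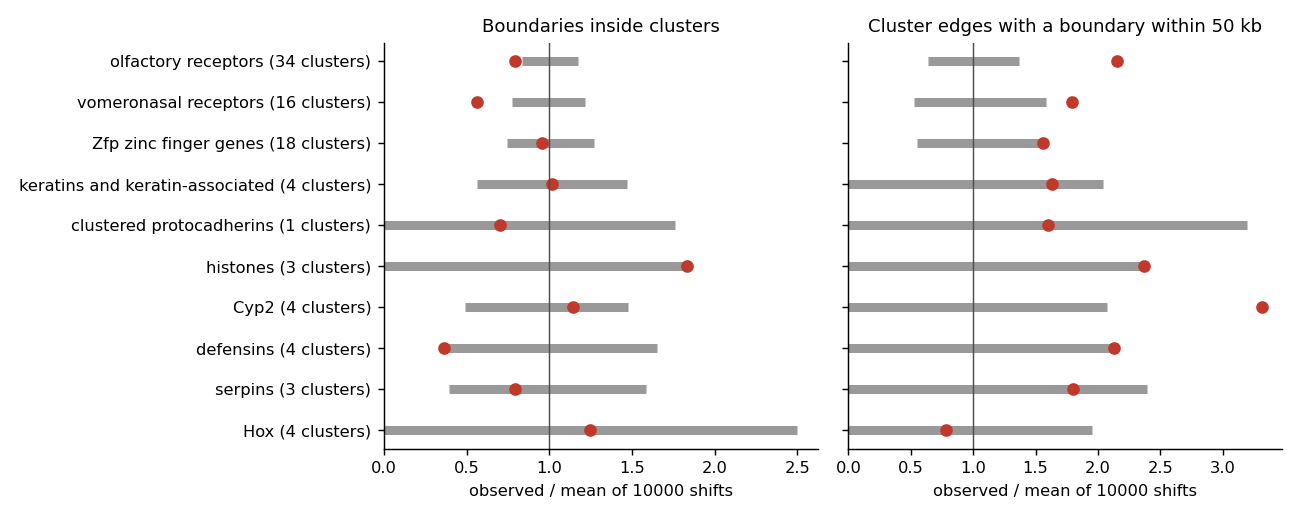
Boundaries inside clusters (left) and cluster edges with a boundary within 50 kb (right) for 10 gene families, as points showing the observed number over the mean of 10000 shifts; grey bars are 95% ranges of the shifts. At the edges, OR clusters are at 2.15, vomeronasal clusters at 1.79 and Cyp2 clusters at 3.31.

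Within Hox and protocadherin clusters, boundaries were found at a few positions. On chromosome 2 a Strong boundary (score 1.04) lay 0.809 kb from the TSS of Hoxd13, the last gene at the posterior end of the Hoxd cluster, and none lay inside that cluster. The Hoxa cluster on chromosome 6 had 1 boundary inside, a Weak one (score 0.235) 3.38 kb from the TSS of Hoxa13. The Hoxb cluster on chromosome 11 also had 1 inside, a Weak one (score 0.433) 3.96 kb from the TSS of Hoxb9 and 73.2 kb from the nearer edge. The Hoxc cluster on chromosome 15 had none inside, and the boundaries nearest to its edges lay 169 and 131 kb outside. The clustered protocadherins on chromosome 18 had a Strong boundary (score 1.31) 47.4 kb from the TSS of Pcdhb1, between the alpha and beta genes, and a Weak one (score 0.331) 1.70 kb from the TSS of Taf7.

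Genes for cytosolic ribosomal proteins lay near boundaries more often than other genes. Of 80 such genes, 39 (48.8%) had a TSS within 25 kb of a boundary, against 24.1% of random protein-coding genes matched on local gene density (95% range 15 to 33.8%, two-sided permutation p = 0.0001, adjusted over 12 lists 0.0006). Rps6 at 0.089 kb, Rpl13 at 0.151 kb and Rpl3l at 0.319 kb were the nearest. OR genes lay near boundaries less often than matched protein-coding genes, whose TSSs are themselves concentrated at boundaries. A comparison of OR genes with random positions was not made. Of 1134 protein-coding OR genes, 132 (11.6%) were within 25 kb, against 23.8% of matched genes (95% range 21.3 to 26.3%, adjusted permutation p = 0.0006), and their median distance was 97 kb against 57 kb. The difference in share was -12.1 percentage points at 25 kb, -6.14 at 10 kb and -18.4 at 50 kb. Neighbouring OR genes share boundaries, so this p-value, which treats genes as independent, is too small.

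For the genes that define the mature OSN, no difference from matched genes passed the test. Of 23 such genes, 7 (30.4%) lay within 25 kb of a boundary, against 24.0% at random (adjusted permutation p = 0.676). Gng13, a G protein subunit of odorant signalling, was 0.330 kb from a Strong boundary (score 1.03) and Umodl1 7.14 kb from another (score 0.619). The farthest were Kirrel2 at 170 kb, S100a5 at 131 kb and Ric8b at 99.9 kb. Omp, the olfactory marker protein, was 52.0 kb from a Weak boundary (score 0.464), and Adcy3, the adenylyl cyclase of odorant signalling, 50.6 kb from a Strong one (score 1.34).

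Regulators of OR choice and of OSN identity did not pass the test either, with 7 of 20 genes (35%) within 25 kb against 23.7% at random, a difference of 11.3 percentage points (adjusted permutation p = 0.503). The difference was 18.7 points at 10 kb (adjusted permutation p = 0.0545) and 22.5 points at 50 kb (adjusted permutation p = 0.259), neither past the threshold. Within 10 kb of a Strong boundary were Mef2a (0.357 kb, score 0.618), Ehmt1 (2.11 kb, score 0.855), Emx2 (5.87 kb, score 2.5), Ebf3 (8.06 kb, score 2.66) and Ebf1 (9.82 kb, score 2.31). Atf5 lay 4.16 kb from a Weak boundary (score 0.407). Lhx2, a homeodomain factor that binds OR enhancers, was 13.2 kb from a Weak boundary (score 0.418), and Ldb1, its partner protein, 37.3 kb from a Strong one (score 1.17). Farthest away were Cbx3 at 92.9 kb, Ehmt2 at 91 kb and Cbx5 at 72.3 kb.

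Markers of other cells of the olfactory epithelium gave no call. Within 25 kb of a boundary were 2 of 15 immature OSN genes, 2 of 14 globose basal cell genes, 1 of 9 horizontal basal cell genes and 2 of 18 sustentacular and Bowman gland genes, with shares from 11.1% to 14.3% and adjusted permutation p from 0.503 to 0.65. Among vomeronasal neuron genes it was 4 of 8 (50%, adjusted permutation p = 0.252), with Tfap2e, Gnao1 and Robo2 nearest at 1.26, 2.46 and 5.68 kb, and at 10 kb this list passed (adjusted permutation p = 0.0316). Immune and blood genes had 8 of 15 (53.3%) within 25 kb against 23.9% at random (permutation p = 0.0134, adjusted 0.0536), a difference of 29.4 percentage points. With Strong boundaries alone the list passed (adjusted permutation p = 0.02), and at 50 kb the difference was 16.1 points (adjusted permutation p = 0.419). Of the 8 genes, Hbb-bs, a beta globin gene inside the chromosome 7 OR cluster from Olfr543 to Olfr692, was 0.595 kb from a Strong boundary, while C1qa, C1qb and C1qc share 1 boundary and Hbb-bs and Hbb-bt another. Together the 8 genes rest on 5 boundaries and are not independent, so the p-values of this list are too small. Architectural proteins had 4 of 17 (23.5%, adjusted permutation p = 1), with Ctcf itself 74.1 kb from a Weak boundary, and the genes of glycolysis and the proteasome 10 of 26 (38.5%, adjusted permutation p = 0.252).

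**Figure D5:**
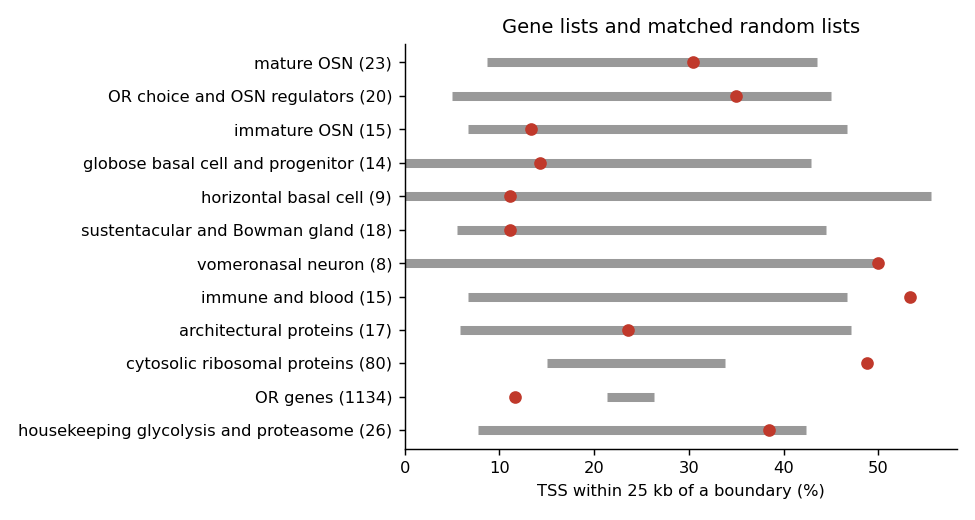
Share of genes with a TSS within 25 kb of a boundary (points, in percent) for 12 gene lists, with the number of genes in brackets; grey bars are 95% ranges of 10000 matched random lists. Ribosomal protein genes are at 48.8%, above their range, and OR genes at 11.6%, below theirs.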

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

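Of 106 alternative values for the main results that have a test, 98 kept their direction and their side of the threshold, and of 186 for single families and lists 158 did, while 7 gained and 3 lost a call. Some alternatives could not differ. Among the 106, 5 equalled the main value, since chromosomes 3, 5, 8, 12 and 18 hold no OR cluster. Leaving out X repeats the setting of autosomes alone, which also left the ratios of the other families unchanged. Of 18 alternative counts of families or lists past the threshold, 12 equalled the count reported. Lists past it numbered 3 in place of 2 with Strong boundaries, with the highest-scoring ones and at 10 kb. Of 7 alternatives for values without a test, 3 moved by less than the SD between chromosomes. The TSS ratio ran from 1.35 to 2.48 over 30 alternatives, the CTCF ratio from 1.08 to 2.86 over 10 and the OR edge ratio from 1.48 to 3.38 over 11. All had a p of 0.0001, by permutation except for the CTCF ratio matched on TSS distance, which used binomial draws. With Strong boundaries alone the density was 1.58 per Mb, the median score was 0.936 by the authors' threshold on it, and the median spacing of 385 kb differed from random placement by -43.4 kb. With the highest-scoring boundaries the spacing of 410 kb differed by -46.9 kb. Fewer boundaries give wider spacing by construction, and the cause of the change in sign was not tested. The density ratio inside OR clusters lost its unadjusted call with neighbouring genes up to 1 Mb apart (0.858) and without chromosome 2 (0.843), 9 (0.818) or 11 (0.828), and was 1.01 against GC-matched windows. The score difference inside OR clusters was 0.132 among Strong boundaries alone, where 27 were left inside, some of them within 50 kb of an edge. Families with changed edges, OR clusters aside, numbered 2 at first, 4 with Strong boundaries alone, 3 with the highest-scoring ones and 0 at a distance of 25 kb. Families without a call changed sides of 1 in density with Strong and with the highest-scoring boundaries: keratins (0.605 and 0.646), Cyp2 (0.719 and 0.769) and Hox (0 and 0), with histones at 0.872 under the latter. The 2 protocadherin edges gave 0 under both settings and at 25 kb and 0.866 at 100 kb, and Hox edges gave 1.57 at 25 kb. Differences from matched lists, in percentage points, changed sign for mature OSN genes (-2.91) and horizontal basal cell genes (0.0122) at 10 kb, sustentacular genes at 50 kb (1.06) and architectural proteins on autosomes (2.11), at 10 kb (0.0776) and at 50 kb (20.9). None of these lists was past the threshold, and the cause was not tested. Calls were gained, again in percentage points over matched lists, for vomeronasal neuron genes at 10 kb (38.8) and for immune and blood genes with Strong (31) and with the highest-scoring boundaries (32.1). Over 8 alternatives each, the differences of other lists kept their direction, from 16.4 to 27.5 points for ribosomal protein genes, 3.68 to 17.3 for glycolysis and proteasome genes, -15.4 to -4.44 for immature OSN genes and -15.1 to -3.91 for globose basal cell genes. The depth of the map is unknown, so what it limits was not assessed. No paired analysis was possible because the 2 replicates belong to 1 group and were combined in 1 list.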

Other observations

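The scores of edge boundaries, the widest intervals and the question of mixed sexes on X were examined only after the values had been seen. The other tests in this part were set out before their results were seen. For read uniqueness inside OR clusters, this does not extend to the condition that the range of shifts leave out the uncorrected ratio.

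The boundaries at the edges of OR clusters were stronger than others. Of the 44 boundaries within 50 kb of an edge, 38 (86.4%) were Strong, against 53.2% of all others, and a random draw from the same chromosomes gave 55.5% (95% range 40.9 to 70.5%, permutation p = 0.0001). Their median score was 1.10 against 0.542 (permutation p = 0.0001).

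The 30 widest intervals between neighbouring boundaries, from 1890 to 11575 kb, were of 2 kinds. In 16 of them under 50% of simulated reads were unique (7.08 to 41.1%), and these included 14 of the 15 widest. They held a median of 28.5 protein-coding genes, and several held tandem families, such as Slx and predicted genes on X, Vmn1r and Vmn2r genes on chromosome 7, Defb genes on chromosome 8 and Mup genes on chromosome 4. In the other 14 intervals 79.9 to 92.7% of reads were unique, and 10 of these held at most 1 protein-coding gene, such as 1910 kb on chromosome 15 with Myc. The widest of the 14, 2695 kb on chromosome 7 (68847501 to 71542500), held 2 protein-coding genes, Nr2f2 and Gm10295.

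Boundaries inside OR clusters were fewer than after shifting before adjustment over families (ratio 0.791, adjusted permutation p = 0.112). GC content may account for this, since the ratio was 1.01 against windows of the same GC content. A lack of CTCF core matches may too, since they were at 19.5 per Mb against 37.8 after shifting (ratio 0.516, permutation p = 0.0017). Boundary number was not compared at equal motif density, so the count of matches cannot decide this. GC content and core matches were not separated from each other. The GC-matched windows were compared for all boundaries only. The 74 boundaries inside include 14 within 50 kb of an edge, so this comparison is not of the interior alone. The lower ratios to shifted boundaries with Strong boundaries (0.511, permutation p = 0.0015) and with the highest-scoring ones (0.447, permutation p = 0.0004) were not tested against such windows. Low read uniqueness remains open. Among well-mapped boundaries the ratio was 0.876 (permutation p = 0.301), within the range of the shifts, so low read uniqueness may account for the lower density as well. That range held both 1 and the uncorrected ratio, so the test cannot decide this. Whether the density differs in other cells was not tested, since there is 1 group.

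Boundaries at the edges of OR clusters were not accounted for by the explanations tested. Promoters of other genes beside the clusters are argued against as the whole cause. Positions at the same distances from non-OR TSSs had a boundary at 23.6 edges against 44 observed (ratio 1.86, p = 0.0001 from binomial draws). The draws treat edges as independent. A step in read uniqueness is argued against as well, since among the 22 edges with a step of at most 5 points 14 had a boundary against 6.53 after shifting (ratio 2.14, permutation p = 0.0011). Strain differences at the clusters and the caller's own filters were not tested and stay open. Whether other cell types have the same edges was not tested here.

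The low share of Strong boundaries on X was not wholly explained by poor mapping alone or by a lack of CTCF matches alone. X did differ in both. Of its boundaries 61.4% were well-mapped, against 88.0% of those on autosomes, and 41.0% had a CTCF core match within 10 kb, against 59.0%. A part played by either, or by both together, was not tested. Among well-mapped boundaries the Strong share was 36.8% on X and at least 49.6% on each autosome, and among boundaries with a CTCF core match it was 40.1% on X and at least 57.1% on each autosome. The mice were of mixed sex, so the X signal could come from single X chromosomes of males together with active and inactive ones of females, and a lower copy number would give fewer contacts. A boundary list of each sex apart would show whether the Strong share on X differs by sex. It would not by itself separate copy number from the inactive X. With 1 list for both sexes, mixed copies of X stay open as a hypothesis for a Strong share on X of 0.577 times the autosome mean.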
